A study of Homo sapiens with 6 samples.

How the data were processed

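RNA-seq was run on 6 libraries of LN229 cells, an established human glioblastoma line. Of these, 3 came from cells transduced with an empty vector and 3 from cells transduced to overexpress LACTB. Per the labels' protocols, total RNA was extracted with Trizol and chloroform and libraries were made with an NEB kit. Per the submitters' processing notes, HISAT2 and the hg38 build were used. The read counter, the annotation, any strand setting and the normalization are not given in the sources used here.

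The deposited table gives 1 signal value per gene and library, a normalized read count, for 24489 rows named by gene symbol. The values were not whole numbers, so they had been adjusted before deposit. Values below 1e-10 were set to 0 here. Low values were checked for a step worth 1 read. The best single step per library left between 29.5% and 50.9% of low values whole at a tolerance of 0.05, against 10% by chance, so read counts were not recovered and no count model was used. The design written before the data were examined had foreseen either counts or values scaled to library size or gene length. Its branch for normalized values was applied to this unit, with the low-value filter set relative to the mean column total.

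Column totals were 41279394, 38049489 and 41384595 normalized counts in the vector libraries and 35683869, 34907394 and 35001626 in the LACTB libraries. The number of reads behind each column is unknown, so no counting interval is given and precision rests on the spread between libraries. Genes above 0 numbered 22538 in each of the 3 vector libraries, and 20809, 20500 and 23061 in LACTB libraries 1, 2 and 3. Why the vector libraries share the same number is not known. The adjustment made before deposit may have altered the spread between libraries, on which every p-value rests. The labels do not say that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

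Values were taken as log2(value + 1), and fold changes are on that scale, which understates the change of low genes. Genes with a mean of at least 1 CPM were tested, where 1 CPM is 37.7 normalized counts, from the mean column total. This left 12942 genes. For 9 symbols that stood on more than 1 row, the row with the higher mean kept the symbol. Groups were compared with limma 3.58.1 in R 4.3.3 (trend and robust settings, group as the only term), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. All differences are LACTB minus vector. Means are given ± SD over 3 libraries.

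Named genes followed a rule fixed before the data were examined. It took LACTB, 8 genes chosen for the study's subject, the 8 largest rises and 8 largest falls among called genes whose groups did not overlap, and up to 3 called members with the smallest adjusted p from each gene list. Some genes that the rule took are not reported here. The gene lists, 31 in all, had been fixed at the same time. Of these, 28 had at least 5 tested members and were tested with limma's camera at a preset correlation of 0.01, adjusted over the 28 lists. Each list median was also set against 10000 random lists, with each member drawn from the 100 genes outside the list nearest to it in mean level. Of 701 list members, 685 were matched to the table, 19 of them under an older symbol, and the rest were not analysed here.

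Gene positions, transcript lengths and GC content came from GENCODE release 29 on GRCh38, in which 94.8% of symbols matched a single gene. The longest transcript stood for each gene. Length and GC were available for 98.2% of tested genes.

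The fit was tested on simulated data with 12899 genes. Changes of 1.41-fold were called for 15.2% of changed genes, 2-fold for 75.8% and 4-fold for 98.4%, and 6 of 12703 unchanged genes were called. Only 66, 66 and 64 genes were changed at these sizes, against 6720 called in the data. The adjustment is stricter when few genes change. The simulated noise was also drawn independently for each gene and library, without a trend with length and GC between the groups. These rates, that of unchanged genes included, therefore do not carry over to the data.

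Alternatives fixed beforehand were median centring, quantile normalization, no filter, a filter at 5 CPM, limma without trend and robust settings, pseudocounts of 0.1 and 0.01, the replicate number as a block, leaving out each library, a 2-fold minimum, an adjusted p threshold of 0.01, and other gene set tests (camera with an estimated correlation or on ranks, and fry). Equal column totals, a pseudocount of 1 CPM, and removal of a spline on transcript length and GC from every library were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.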

Results

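The transcriptome of LN229 glioblastoma cells was measured in 3 libraries of vector-transduced cells and 3 libraries of LACTB-transduced cells. LACTB encodes a serine beta-lactamase-like protein of mitochondria. The comparison asked which genes differ when LACTB is overexpressed, in a study concerned with lipid synthesis, the receptor ERBB3 and the chaperone Hsc70 (HSPA8). Column totals ranged from 34907394 to 41384595 normalized read counts and were lower in all 3 LACTB libraries than in any vector library. Spearman correlations across genes were 0.987 to 0.993 between vector libraries, 0.9957 to 0.9962 between LACTB libraries, and 0.952 to 0.969 between groups.

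LACTB itself (chromosome 15, 63121800 to 63142061, plus strand, GRCh38) rose from 455 ± 61.4 normalized counts in vector cells to 4183 ± 96.3 in LACTB cells (SD, n = 3 each), which was 9.22-fold. The log2 difference was 3.21 (SE 0.13, limma adjusted p = 2.9e-14). The 3 vector libraries held 458, 515 and 393 and the 3 LACTB libraries 4268, 4078 and 4203.

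Of the 8 genes chosen for the study's subject, FASN, SCD, SREBF1 and ACLY fell, and ERBB3, HSPA8, ACACA and PISD did not pass the threshold. FASN, the fatty acid synthase (chromosome 17, 82078333 to 82098332), fell from 54841 ± 13014 to 29728 ± 1500 normalized counts, a log2 difference of -0.85 (SE 0.14, adjusted p = 4.6e-05). SCD, which desaturates stearoyl-CoA (chromosome 10, 100347124 to 100364834), fell by 0.80 on the log2 scale (adjusted p = 5.8e-06). SREBF1, a transcription factor of lipid synthesis genes (chromosome 17, 17810399 to 17837002), fell by 0.77 (adjusted p = 3.5e-05). ACLY, which makes cytosolic acetyl-CoA (chromosome 17, 41866908 to 41930542), fell by 0.37 (adjusted p = 0.0075). Its call was lost with quantile normalization (adjusted p = 0.13), with equal column totals (0.15) and without LACTB library 2 (0.054). Transcripts of ERBB3 (chromosome 12, 56076799 to 56103505) stood at 14266 ± 1587 in vector and 14425 ± 1325 in LACTB cells, a log2 difference of 0.02 (SE 0.12, adjusted p = 0.91). HSPA8 (chromosome 11, 123057489 to 123063230) stood at 84101 ± 21914 and 78801 ± 4310, a difference of -0.06 (SE 0.14, adjusted p = 0.72). With quantile normalization the HSPA8 difference was 0.33 (adjusted p = 0.023), and without vector library 1 it was 0.14. ACACA, an acetyl-CoA carboxylase (chromosome 17, 37084988 to 37406818), differed by -0.08 (adjusted p = 0.57), and by -0.44 once transcript length and GC were removed (adjusted p = 0.00018). PISD, a mitochondrial phosphatidylserine decarboxylase (chromosome 22, 31618491 to 31662432), differed by 0.16 (adjusted p = 0.26). It passed the threshold with equal column totals (0.35, adjusted p = 0.017) and with length and GC removed (0.42, adjusted p = 0.000565). After that removal the window of 50 neighbouring tested genes that holds PISD had a median of 0.23.

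**Figure D1:**
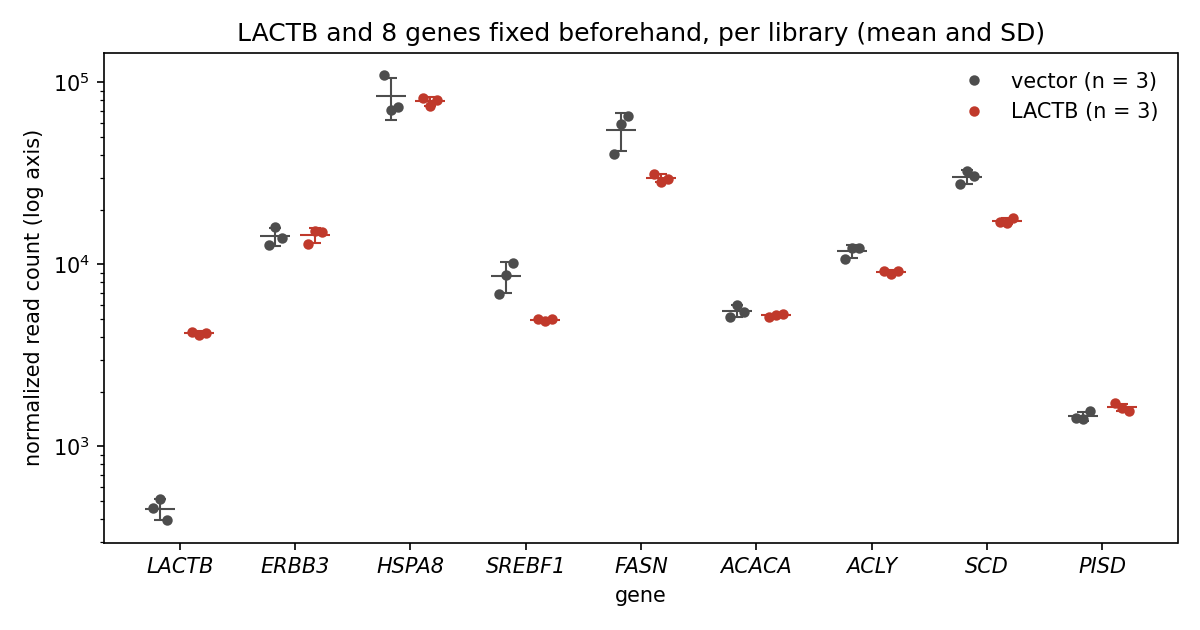
Normalized read counts (log axis) of LACTB and the 8 genes fixed beforehand, with each library as a point and the mean and SD of 3 libraries as a bar, for vector (grey) and LACTB (red). LACTB is 9.22-fold higher in LACTB cells, FASN, SCD, SREBF1 and ACLY are lower, and the ERBB3 and HSPA8 groups overlap.

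Across the transcriptome, 3543 genes were higher and 3177 lower with LACTB among 12942 tested, so 6720 genes (51.9%) passed the threshold. Of these, 2749 differed by less than 1.5-fold, while 820 rose and 580 fell by at least 2-fold. The 2 groups did not overlap for 59.7% of tested genes, against 10% by chance. The split between directions depended on the scaling of the libraries. Higher genes made up 52.7% of calls as deposited, 39.3% after median centring and 72.2% with equal column totals, and the last shifted the median difference of all genes from 0.05 to 0.24.

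The largest rises were from low levels. GALNT5, a glycosyltransferase of mucin-type O-glycosylation (chromosome 2, 157257598 to 157314211), rose from 62.8 ± 13.2 to 1004 ± 118, and TAS1R1, a taste receptor subunit (chromosome 1, 6555181 to 6579757), from 21.2 ± 5.35 to 386 ± 7.11. The non-coding RNA LINC00221 rose from 3.54 ± 5.10 to 182 ± 12.4, the cadherin CDH6 from 4.31 ± 2.01 to 105 ± 27.3, CSMD3 from 5.04 ± 1.15 to 115 ± 31.6, and the zinc-finger gene ZFHX4 from 9.73 ± 1.26 to 162 ± 21.03. The cancer-testis genes SSX1 (28.7 ± 10.1 to 469 ± 40.6) and PAGE2 (17.9 ± 9.39 to 340 ± 48.4) belong to families of near-identical copies, so their values are uncertain. Among the largest falls, DCT, the melanin synthesis enzyme dopachrome tautomerase (chromosome 13, 94436808 to 94479682), fell from 1776 ± 266 to 57.7 ± 30.5, a log2 difference of -5.09 (SE 0.35, adjusted p = 9.7e-08). DUSP9, a phosphatase of MAP kinases, fell from 306 ± 74.8 to 10.9 ± 10.8. The potassium-dependent sodium-calcium exchanger gene SLC24A4 fell from 248 ± 23.8 to 10.6 ± 5.68, CSMD2 from 210 ± 53.9 to 9.13 ± 5.76 and the cytokine receptor gene IL2RB from 164 ± 32.0 to 4.64 ± 2.80. The cytokine gene IL24 fell from 122 ± 28.8 to 0.913 ± 1.57 and SAA1, which has near-identical copies, from 102 ± 29.3 to 2.37 ± 2.74. HTN1 had a mean of 238 ± 51.9 in vector cells and stood at 0 in all 3 LACTB libraries once values below 1e-10 were set to 0. Adjusted p for these 16 genes was at most 1.0e-07.

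The differences followed transcript length and GC content. Across genes, which are not independent replicates, the log2 difference had a Spearman rho of 0.41 with transcript length and -0.45 with GC, and the 2 properties accounted for 21.3% of its variance. The median difference went from -0.27 in the shortest of 5 equal bins of genes to 0.46 in the longest. All 3 LACTB libraries lay on one side and all 3 vector libraries on the other, for length and for GC. After the trend was removed 6176 genes passed, and 4302 of them were among the 6720, 25 of these in the opposite direction.

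**Figure D2:**
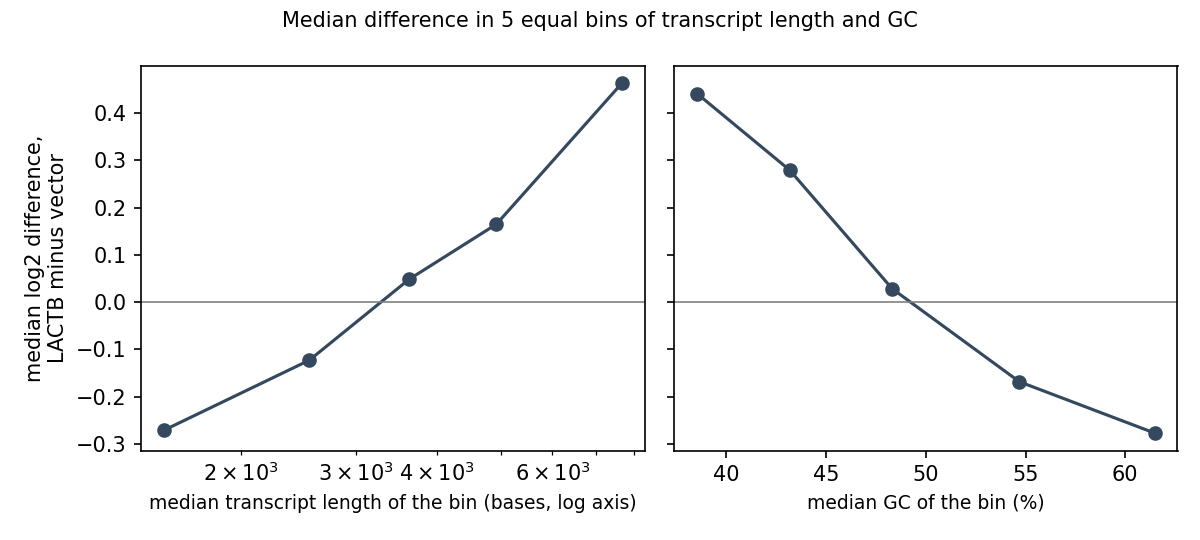
Median log2 difference (LACTB minus vector) of tested genes in 5 equal bins of transcript length (left, bases on a log axis) and of GC content (right, percent), each point a bin. The median rises from -0.27 to 0.46 with length and falls from 0.44 to -0.28 with GC.

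Cholesterol synthesis genes were lower with LACTB. Of 25 members 18 fell, 1 rose and 6 did not pass, with a median log2 difference of -0.55 (camera adjusted p = 1.4e-05, and adjusted p = 0.44 with an estimated correlation). The value 0.44 recurs below because the adjustment gave many lists the same value. Unadjusted, camera with an estimated correlation gave p = 0.021 for this list, 0.056 for glycolysis and 0.31 for mitochondrially encoded genes. FDPS, which makes farnesyl diphosphate, fell from 10980 ± 1406 to 5181 ± 72.8, DHCR7, a last-step reductase, fell by 0.90 on the log2 scale, and the sterol sensor INSIG1 fell by 0.82. The member that rose was LBR, singled out after its values were seen, a sterol reductase that is also a nuclear envelope protein. After length and GC removal 17 members fell and the median was -0.52, and with equal column totals 15 fell and it was -0.36. Windows of 50 neighbouring tested genes had medians after length and GC removal of -0.34 around DHCR7, 0.23 around INSIG1 and -0.04 around FDPS.

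The fatty acid synthesis list went both ways. Of 26 members 8 rose and 9 fell, or 10 fell when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.29). With median centring 4 rose and 11 fell, and with equal column totals 8 rose and 6 fell. The 3 members with the smallest adjusted p all fell, namely ACSS2, which activates acetate, by 1.30, the desaturase FADS2 by 1.09 and SCD by 0.80. FASN, also in the list, fell by 0.85. Fatty acid oxidation genes fell in 12 of 24 cases and rose in 4 (median -0.30, camera adjusted p = 0.018, and adjusted p = 0.44 with an estimated correlation). CPT1C, a neuronal carnitine palmitoyltransferase family member, fell by 2.18, the acyl-CoA dehydrogenase gene ACADS by 1.05 and the electron carrier gene ETFB by 1.03. With equal column totals 9 of the 24 fell, 5 rose and the median was -0.11. Of 21 glycerolipid and lipid droplet genes 5 rose and 10 fell (camera adjusted p = 0.19). The monoacylglycerol lipase gene MGLL rose by 1.498 and GPAT3 by 0.93, and the lipase gene LIPE fell by 1.13. The counts were 5 and 6 with equal column totals. Of 21 phospholipid synthesis genes 2 rose and 6 fell (camera adjusted p = 0.19), with PCYT2 lower by 0.89, CDIPT lower by 0.72 and PCYT1A higher by 0.57. Under equal column totals 3 rose and 2 fell (median -0.002), and under median centring 2 rose and 10 fell. Except where a second count is given, counts adjusted over the list alone equalled those over all genes in every list.

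Members of the ERBB list were mostly higher. Beside receptors and ligands it holds adaptor and regulator genes, such as GRB2, CBL and ERRFI1, and the counts do not separate these kinds. Of 18 members 11 rose, 3 fell and 4, among them ERBB3, did not pass (median 0.61, camera adjusted p = 0.018, and adjusted p = 0.44 with an estimated correlation). The receptor gene ERBB2 rose from 3894 ± 553 to 8801 ± 429, the ligand gene NRG1 from 146 ± 14.3 to 439 ± 114 and the ligand gene EREG from 21.7 ± 7.87 to 118 ± 12.8. The list missed the threshold under a filter at 5 CPM (adjusted p = 0.066). In the PI3K, AKT and MTOR list 14 of 26 members rose and 4 fell (camera adjusted p = 0.082). PIK3R1 rose by 1.46, PIK3CA by 1.06 and FOXO3 by 0.78. With length and GC removed 7 members rose and the median moved from 0.38 to 0.09, with median centring 9 rose and 5 fell, and with equal column totals 18 rose and none fell. Of 19 ERK feedback genes 6 rose and 5 fell (camera adjusted p = 0.85), and the median of 0.14 and the test differed in sign. The counts were 10 and 4 with equal column totals and 3 and 6 with median centring. SPRY1 fell by 2.48 and ETV4 by 1.45, and ETV1 rose by 0.69, a call lost with length and GC removed (adjusted p = 0.29).

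Glycolysis genes fell in 16 of 22 cases, with 1 rise (median -0.50, camera adjusted p = 1.3e-05, and adjusted p = 0.44 with an estimated correlation). The lactate exporter gene SLC16A3 fell from 6616 ± 839 to 1991 ± 85.7, the aldolase gene ALDOC from 840 ± 15.3 to 126 ± 26.4 and the phosphofructokinase gene PFKL by 1.15. Equal column totals gave 11 falls, 2 rises and a median of -0.31. Nuclear genes of oxidative phosphorylation fell in 18 of 28 cases with no rise (median -0.44, camera adjusted p = 4.7e-05, and adjusted p = 0.44 with an estimated correlation). The smallest adjusted p were those of ATP5PO (-0.94), NDUFV1 (-0.85) and COX7A2 (-0.83). With equal column totals 13 fell, 1 rose and the median was -0.24. Some of these genes lie where neighbouring genes were lower too. After length and GC removal, windows of 50 neighbouring tested genes had medians of -0.33 around ATP5PO and -0.46 around PFKL, both on chromosome 21. The median was -0.34 around NDUFV1, 0.03 around COX7A2 and 0.003 around ALDOC. Mitochondrially encoded genes fell in 7 of 13 cases, or 8 when adjusted over the list alone (median -0.39, camera adjusted p = 0.022, and adjusted p = 0.44 with an estimated correlation). MT-ND6 fell by 0.71, MT-ND3 by 0.57 and MT-ATP6 by 0.48, and the list's call was lost with quantile normalization (adjusted p = 0.87), as were those of MT-ND3 (0.24) and MT-ATP6 (0.39), and the list's also without LACTB library 3 (0.074). Under quantile normalization 3 of the 13 rose and 2 fell. With equal column totals 5 fell, 0 rose and the median was -0.20 (camera adjusted p = 0.038). The mitochondrially encoded list took 2.95%, 3.15% and 3.18% of the vector columns and 2.94%, 3.19% and 2.86% of the LACTB columns, so its share of the columns overlapped between groups. Of the 13 lists that passed camera this was the only one whose median lay inside the central 95% of 10000 lists matched on mean level, at percentile 41.6 with a matched median of -0.37. In the hypoxia list 3 of 18 members rose and 7 fell, or 9 when adjusted over the list alone (camera adjusted p = 0.12, and 0.018 with length and GC removed). ANGPTL4 fell from 4171 ± 603 to 740 ± 133, and STC2 rose from 449 ± 51.2 to 2557 ± 470. In the hypoxia list 4 members rose and 5 fell with equal column totals.

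All 28 ribosomal protein genes tested were lower with LACTB (median -0.85, camera adjusted p = 9.6e-13, and adjusted p = 0.44 with an estimated correlation). RPS3 fell by 1.44, RPL7 by 1.40 and RPL27 by 1.16, all genes with many processed pseudogene copies, so their values are uncertain. The list took 5.44%, 4.47% and 4.96% of the vector columns and 3.20%, 3.09% and 3.14% of the LACTB columns. The median was -0.43 with 21 of the 28 called lower under quantile normalization, -0.66 with 26 under equal column totals, and -0.62 with 27 once length and GC were removed.

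Genes of the G2 and M phases rose in 16 of 30 cases and fell in 1 (median 0.38, camera adjusted p = 0.012, and adjusted p = 0.44 with an estimated correlation). The kinetochore gene CENPF rose from 598 ± 39.5 to 1618 ± 231, KIF23 by 1.11 and BUB1 by 1.10. The member that fell was the phosphatase gene CDC25B, singled out after its values were seen, a call lost with quantile normalization (adjusted p = 0.063) and equal column totals (0.10). With median centring 13 rose and 5 fell (median 0.25), and with equal column totals 18 rose and none fell (0.57). Of 28 S phase genes 10 rose and none fell (median 0.21, camera adjusted p = 0.030, and adjusted p = 0.44 with an estimated correlation), with HELLS higher by 1.21, CLSPN by 1.09 and E2F8 by 0.91. The S phase count depended on the scaling, with 19 higher under equal column totals (median 0.41), 16 under quantile normalization (0.35), and 7 higher and 2 lower after median centring (0.08). Without vector library 2 the G2 and M list reached an adjusted p of 0.051 and the S phase list 0.069. The S phase list also reached 0.073 without LACTB library 1, 0.072 with median centring and 0.053 with the replicate number as a block. Of 6 replication-dependent histone genes 3 rose (camera adjusted p = 0.37), namely HIST1H4H by 0.96, HIST1H2AC by 0.46 and HIST1H1C by 0.41, and the HIST1H2AC call was lost when any of 5 libraries was left out, all but vector library 1, and with median centring (adjusted p = 0.11), quantile normalization (0.23) and limma without trend and robust settings (0.065). The HIST1H1C call was lost without vector library 2 (adjusted p = 0.087), without LACTB library 1 (0.060) and with median centring (0.10).

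Stress lists were mixed. Of 29 chaperone genes 3 rose, or 2 when adjusted over the list alone, and 8 fell (camera adjusted p = 0.18). The small heat shock gene CRYAB fell from 2305 ± 179 to 584 ± 50.9, HSPA1A by 0.78 and HSPA1B by 0.71, and the last pair are near-identical copies. Of 26 genes of the ATF4 and unfolded protein responses 5 rose and 8 fell (camera adjusted p = 0.24). The cystine transporter gene SLC7A11 rose by 1.92, SEL1L rose by 1.19 and DDIT4 fell by 1.26. Of 25 p53 target and apoptosis genes 6 rose and 8 fell (camera adjusted p = 0.36), with GDF15 lower by 1.31, BBC3 by 1.20 and BID by 1.02. Of 24 lysosome and chaperone-mediated autophagy genes 3 rose and 9 fell (camera adjusted p = 0.19). LAMP2, a lysosomal membrane protein, rose by 0.97, WIPI1 fell by 0.96 and GABARAPL1 fell by 0.83. Medians of these 4 lists were negative as deposited and positive with equal column totals, under which rises and falls numbered 9 and 7 for chaperones, 7 and 5 for the ATF4 list, 8 and 6 for p53 targets and 7 and 6 for lysosome genes. The lysosome counts were 8 and 7 with quantile normalization and 9 and 7 with length and GC removed, and the chaperone counts 7 and 8 with quantile normalization. Immediate early genes fell in 11 of 19 cases and rose in 2 (median -0.57, camera adjusted p = 0.0060, and adjusted p = 0.44 with an estimated correlation), with JUNB lower by 1.36, NR4A1 by 1.24 and ATF3 by 1.20. The call was lost with length and GC removed (adjusted p = 0.059), and with equal column totals 9 fell, 3 rose and the median was -0.38.

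In the NF-kB and cytokine list 10 of 16 members fell and 3 rose (median -0.61, camera adjusted p = 0.018, and adjusted p = 0.44 with an estimated correlation). The chemokine gene CXCL1 fell from 652 ± 68.4 to 140 ± 30.7, while CCL2 rose from 2011 ± 206 to 7159 ± 519 and LIF from 4403 ± 298 to 13246 ± 2752. With length and GC removed the list's adjusted p was 0.13. Of 29 interferon response genes 12 rose and 7 fell (camera adjusted p = 0.32), with OAS3 higher by 0.83 and IFI35 lower by 0.83. Without vector library 3 only 5 rose and 7 fell, and with equal column totals 17 rose and 5 fell. Mesenchymal and extracellular matrix genes rose in 15 of 28 cases and fell in 6, or 7 when adjusted over the list alone (median 0.40, camera adjusted p = 0.045, and adjusted p = 0.54 with an estimated correlation). With median centring 11 rose and 8 fell, and with equal column totals 17 rose and 3 fell. THBS1 rose from 6031 ± 1377 to 24508 ± 3958 and TGFBI from 6276 ± 94.9 to 23408 ± 2459. The list's call was lost with length and GC removed (adjusted p = 0.11), with equal column totals (0.064), with no filter (0.055), on ranks (0.096) and without vector library 1 (0.21).

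Markers of glial cells went both ways. Of 8 tested astrocyte markers 6 fell and 2 rose (median -1.10, camera adjusted p = 0.0045, and adjusted p = 0.44 with an estimated correlation). ALDOC fell by 2.76, the apolipoprotein gene APOE from 4716 ± 802 to 1023 ± 88.9 and the glutamine synthetase gene GLUL by 0.99. The members that rose, singled out after their values were seen, were the intermediate filament gene GFAP, from 74.5 ± 1.89 to 122 ± 3.82 (log2 difference 0.70, adjusted p = 0.017), and the gap junction gene GJA1, by 0.69 (adjusted p = 0.0015). The GFAP call was lost without LACTB library 2 (adjusted p = 0.052) and without LACTB library 3 (0.065), and GFAP did not reach the filter at 5 CPM. Of 8 oligodendrocyte markers 4 fell and 2 rose (camera adjusted p = 0.26). The myelin genes MBP and MAG fell by 3.01 and 2.13, and UGT8 rose by 0.73. Equal column totals gave 3 rises and 3 falls in this list. Of 8 neuron markers 3 rose and none fell (camera adjusted p = 0.57), namely SYT1 by 1.65, GAP43 by 0.91 and MAP2 by 0.78, and the median of -0.08 and the test differed in sign. The MAP2 call was lost with length and GC removed (adjusted p = 0.29). Of 17 glioma stem and neural progenitor genes 6 rose and 3 fell (camera adjusted p = 0.19), with SOX2 higher by 1.24, ITGA6 by 1.14 and MYCN lower by 2.80. With equal column totals 12 rose and 2 fell (median 0.46, against 0.26), and with median centring 3 rose and 3 fell. Too few markers of other cell types were tested for a list test. Of 4 epithelial markers KRT14 rose by 0.96 and KRT18 and KRT8 fell by 1.15 and 1.01, the single immune marker tested, CD68, rose by 0.59, and neither of 2 endothelial markers passed.

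Several list counts also rested on single libraries. With any library left out, rises ran from 9 to 15 and falls from 0 to 6 in the PI3K list, from 3 to 7 and from 4 to 5 in the ERK list, from 2 to 6 and from 7 to 9 among chaperones, from 2 to 5 and from 5 to 9 in the ATF4 list, from 5 to 14 and from 6 to 7 among interferon genes, and from 4 to 7 and from 2 to 3 among stem and progenitor genes. Rises ran from 7 to 14 among S phase genes, from 1 to 3 among histone genes and from 2 to 4 in both the hypoxia and the lysosome list. Falls ran from 1 to 4 among G2 and M genes, from 5 to 9 among mitochondrially encoded genes, from 4 to 7 among phospholipid genes and from 4 to 8 among mesenchymal genes. In the ribosomal and the NF-kB lists no count changed.

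**Figure D3:**
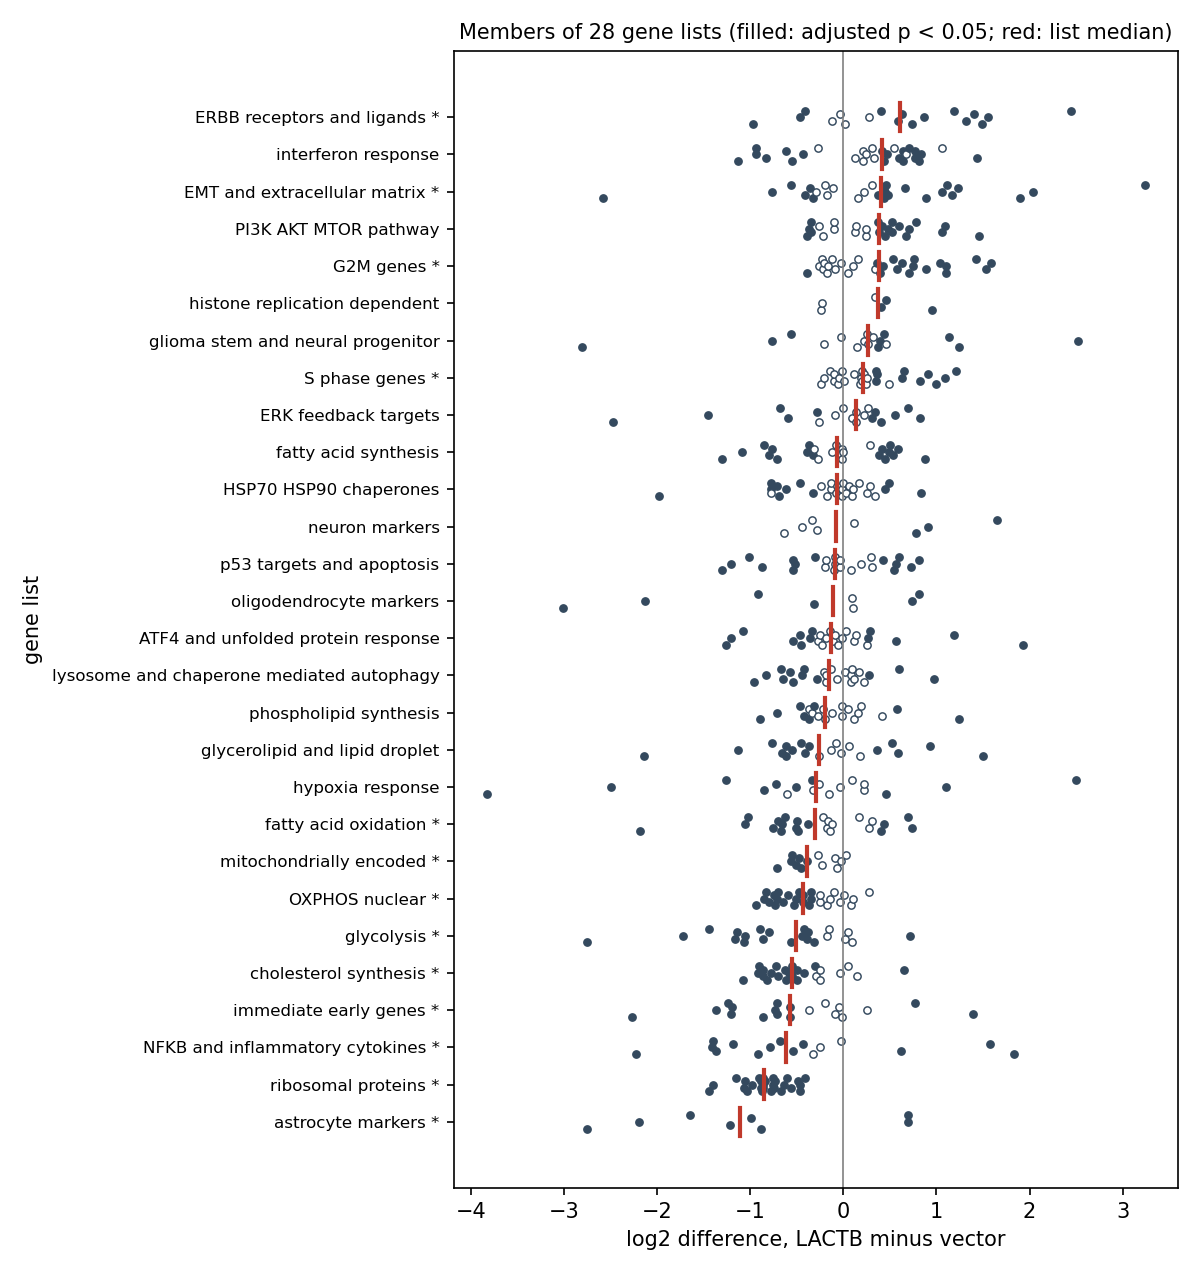
Log2 difference (LACTB minus vector, horizontal axis) of each tested member of 28 gene lists, filled where the adjusted p passed the threshold, with the list median in red. An asterisk marks the 13 lists that passed camera at the preset correlation. Among them ribosomal proteins (median -0.85) and cholesterol synthesis (-0.55) lie below 0. The list labelled ERBB receptors and ligands, which also holds adaptors and regulators, lies above it (0.61).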

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

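The level of LACTB kept its direction and call under all 17 alternatives (log2 difference 3.02 to 3.40). Of 109 other named genes, 101 kept direction and side of the threshold under every alternative fixed beforehand, and 98 under the 3 added after seeing the data as well. Of 28 lists, 18 and 15 did so, other set tests aside. Under the filter at 5 CPM only 92 of the 109 genes were tested, and the histone list had too few members for a test. What that filter left out was judged on the other alternatives. The cause of the changes below was not tested. Genes passing numbered 5344 to 7340 when any library was left out. Lower genes numbered 1913 with equal column totals, against 3177. With a 2-fold minimum 1400 genes passed, 820 higher and 580 lower. With an estimated correlation 0 of the 28 lists passed, although 7463 genes had an unadjusted p under 0.05, and fry, which does not compare a list with other genes, passed 25. ERBB3 was -0.11 with median centring, -0.057 with length and GC removed, and -0.056 to 0.10 with a library left out. HSPA8 was 0.33 with quantile normalization, 0.13 with equal column totals and -0.18 to 0.14 with a library left out. ACACA was 0.078 with quantile normalization and 0.11 with equal column totals. Quantile normalization also turned the test's direction for ATF4 (median -0.013), ERK feedback (0.27), lysosome (0.00121) and mitochondrially encoded genes (-0.060). The ERK list turned as well with equal column totals (0.33), on ranks (0.14) and without vector library 2 or 3 (0.0064 to 0.18 over all libraries left out), the ATF4 list with length and GC removed (0.029), and the histone list with no filter (-0.24). The PI3K list passed with quantile normalization and with no filter.

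With the replicate number as a block, 6878 genes passed, 6644 of them among the 6720, and the S phase list missed the threshold (adjusted p = 0.053). Deviations of same-numbered libraries correlated at 0.02, 0.18 and 0.00, and not every library correlated best with its own number, so the numbers were not taken to pair the libraries. The read depth behind the columns is unknown, so small differences can be missed. Simulated changes of 1.41-fold were called in 15.2% of cases. Only 66 genes were changed by that much, against 6720 called in the data, so that rate is not an estimate for these data.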

Other observations

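Tests of the cancer-testis families, of the pigment-making genes, of abundant melanocyte transcripts, of the scaling of the libraries, of the 19 autosomes apart from chromosomes 7, 21 and 22 and of windows of neighbouring genes were chosen after the results were seen. The length and GC correction was likewise added after seeing the data. Bootstrap intervals below are over genes, treated as independent, so they do not measure the spread between libraries.

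The rises of PAGE2 and SSX1 prompted a look at X-linked cancer-testis families, genes normally active in testis and switched on in many tumours. Of 17 tested members of the MAGE, SSX, PAGE, XAGE, GAGE and SAGE families, 6 were higher by at least 2-fold (35.3%, against 6.34% of all tested genes, two-sided Fisher's exact p = 0.00043) and 2 were lower by as much. Without a minimum size 7 passed as higher and 5 as lower. Without PAGE2 and SSX1, which prompted the test, it was 4 of 15 (exact p = 0.012). The filter kept genes with a mean of at least 37.7 normalized counts over all 6 libraries. Among the 6 genes, PAGE2 (17.9), SSX1 (28.7), MAGEB16 (18.4), SAGE1 (6.51) and MAGEC2 (24.4) lay below that in vector cells. They were tested only because they were higher with LACTB, and only MAGEB2 lay above it in both groups. Genes kept in this way must show a rise, and the comparison was not matched on level. Neither p-value therefore shows an excess of rises. MAGEB16 rose from 18.4 to 198 normalized counts and MAGEB2 from 441 to 1303, while MAGEA1 fell from 1846 to 862 and GAGE12J from 782 to 82.4. The members thus went both ways and are not shown to have risen as a group, and reads shared between near-identical copies may have moved between them.

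The number of genes that passed, 6720, was set against chance and against changes of whole chromosomes. The 6 libraries allow only 10 splits into 3 and 3, of which 1, the real one, gave as many genes and the highest other gave 1, and 10 splits are too few for a share under 0.05. After length and GC removal the median of chromosome 21 was -0.38 (95% bootstrap interval -0.48 to -0.23), that of chromosome 7 was 0.26 and that of chromosome 22 was 0.20, each with all 3 libraries of a group on one side, so a copy number difference between the transduced populations may contribute there and cannot be told apart from an effect of LACTB. On the other 19 autosomes medians were at most 0.14 in size, yet 48.2% of genes passed. Chromosomes 7, 21 and 22 held only 1047 tested genes, so a high share elsewhere was certain from the number of calls. Their own copy number is thus too little to account directly for the calls on other autosomes. Whether a change of these chromosomes acts on genes elsewhere was not tested. Neighbouring genes did move together. Medians of 235 windows of 50 neighbouring tested genes ran from -0.46 to 0.45 with an SD of 0.150, against 0.076 on average and 0.086 at most over 1000 permutations of gene positions (p = 0.001), and neighbouring windows on the short arm of chromosome 5 stood at 0.41 and 0.45. Gains or losses of such segments may contribute there, and cannot be told apart from regulation shared by neighbours, since no DNA was analysed here. In the 120 windows with a median within 0.1 of 0, 46.4% of genes passed. This argues against gains or losses of segments of 50 or more genes as the direct cause for those genes. It does not speak to effects of such segments on genes elsewhere. Changes of smaller segments, clonal drift of the populations and a library difference that follows the groups stay open, and the labels give no batch by which to separate them.

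Lower ribosomal protein and cholesterol synthesis genes could reflect the trend with transcript length and GC, a fall of abundant genes as a class, or the scaling of the libraries. Removing the trend left the ribosomal median at -0.62 (95% bootstrap interval -0.76 to -0.45, from -0.85) and the cholesterol median at -0.52 (-0.74 to -0.27, from -0.55). These values argue against the trend, as measured on the longest transcript of each gene, as the whole cause of either. The expressed transcript may be shorter, so part of a length trend may remain. Among 10000 lists matched on mean level, the percentile of the list median was 0 for both, with matched medians of -0.28 and -0.09. The highest ribosomal median under median centring, quantile normalization and equal column totals was -0.43 (-0.53 to -0.30), which argues against scaling as the whole cause. The highest cholesterol median was -0.36 (-0.53 to -0.11, equal column totals), whose interval passes the bound of -0.2, so scaling stays open there, although the list passed camera under all of these (adjusted p at most 0.00023). The trend, the mean level and the scaling were each tested alone. Whether they account for the falls together was not tested. A lower level of these transcripts with LACTB is a hypothesis that these single tests leave standing, for cholesterol synthesis apart from scaling, and neither list passed with an estimated correlation. Reads shared with pseudogenes were not tested, and the normalization applied before deposit is unknown.

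DCT stood at 47.1 CPM in vector cells and 1.53 CPM in LACTB cells, and melanocytic cells mixed into the vector libraries might account for it. The other tested markers of a list of 16 melanocyte genes had a median difference of -0.37 (95% bootstrap interval -1.49 to -0.28), which does not reach the fall of 2 set for such a mixture. The interval is too wide to exclude it alone. Several of these markers are also high in LACTB cells, such as SOX10 (1111 CPM) and S100B (384 CPM). Cells mixed into the vector libraries could hardly make those fall that far, so this median does not decide the question. Melanocytic cells would also bring their abundant transcripts, yet 3 of 4 stood below 10% of DCT in every vector library, namely MLANA (0.36 CPM in vector and 0.31 CPM in LACTB cells), TYRP1 (0.11 and 0.61) and TYR (0.74 and 0), which argues against such a mixture. Of the 4, PMEL (10.1 to 2.67 CPM) and TYR were lower along with DCT. A melanocytic programme in both groups met the bound set beforehand, with 6 markers besides DCT at 10 CPM or more in both, but SOX10, S100A1, S100B and EDNRB are also active in glia, which leaves MITF and MC1R. The check of pigment genes added for that reason found 0 of 7 at 10 CPM or more in both groups. That bound was replaced, after its value was seen, by the filter of 1 CPM, at which 1 of 7, PMEL, stood in both, which leaves open whether pigment-making genes are expressed in both. Whether DCT fell with a wider change of glial and neural crest genes, among them MITF (-1.49), S100B (-1.22) and PMEL (-1.91), was not tested.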
